A study of Mus musculus with 9 samples.

How the data were processed

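Small RNA was profiled by PANDORA-seq in 9 libraries of mouse atrial appendages, 3 from each of 3 groups: young mice of 5 months, old mice of 18 months, and old mice given curcumin. Per the labels, total RNA was treated with AlkB and with T4 polynucleotide kinase, a gel fraction of 15 to 45 nucleotides was taken, adapters of a QIAGEN miRNA kit were ligated, and inserts were read from 1 end over 75 cycles on an Illumina instrument. The submitters' processing notes name cutadapt 2.5 and the genome build mm10. The annotation tool, its settings and the handling of molecular identifiers are not given in the sources used here. The deposited value of each annotation is in expected counts: a read that matched several annotations of a class was divided among them, so that some values are fractions, and no normalization had been applied. The class names in the files point to miRBase, GtRNAdb, mitotRNAdb, rRNAdb, YRNAdb, piRNAdb, Ensembl and Rfam.

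A feature was 1 miRNA precursor, 1 part of 1 tRNA species (5′ end, 3′ end without CCA, CCA end, or the remaining reads of that species, called the other part), 1 rRNA, 1 Y RNA, or 1 Ensembl or Rfam class. Reads that matched the genome and reads that did not were summed for each feature, class totals were left out so that no read was counted more than 1 time, and expected counts were rounded to whole numbers. The 9 files held 996 features, of which filterByExpr of edgeR kept 520 for testing: 277 tRNA fragments (tsRNAs; 185 nuclear, 88 mitochondrial, 4 from precursors), 209 miRNAs and 34 others. Between 83.7% and 87.3% of the clean reads of a library fell in features. Clean reads ranged from 12899427 to 19707803 per library. Shares of reads carry 95% Wilson intervals of at most 0.0225 percentage points to either side, which cover counting error only, since reads are not independent molecules.

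All 9 libraries entered 1 quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 (robust, TMM scaling, group as the only term), and 3 comparisons were drawn from it. A feature counted as changed when its Benjamini-Hochberg adjusted p over all 520 features was under 0.05. CPM were computed by edgeR from feature reads with TMM scaling. The groups, this test, the gene lists, the rule for naming features and the alternatives listed first below were fixed before the data were examined. Where fewer than 5 features passed, the rule named the 10 features with the smallest p in each comparison. It also named the 10 most abundant tsRNAs and up to 4 abundant members of each list. Shares of clean reads were compared by exact two-sided permutation tests, which cannot give a p under 0.1 with 3 libraries against 3, and by exact sign-flip tests over the replicate numbers, which cannot give a p under 0.25. The permutation p were adjusted over 20 shares, and the sign-flip p were left unadjusted.

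The lists of miRNAs covered striated and cardiac muscle, fibrosis, the miR-30 and let-7 families, senescence, miR-17-92 and its paralogue clusters, inflammation, the Dlk1-Dio3 imprinted cluster, atrial fibrillation, and markers of endothelial cells, smooth muscle, red blood cells (erythroid), leukocytes, epithelium, neurons and liver. Further lists held the nuclear tRNA 5′ ends, 3′ ends, CCA ends and other parts, mitochondrial tRNA, precursor tRNA, cytoplasmic rRNA, mitochondrial rRNA, Y RNA, snoRNA, snRNA, piRNA and the nuclear tRNA fragments of each amino acid. Lists with at least 3 tested members, 42 in all, were tested by camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, again with an estimated correlation, and by fry. The other 9 lists were too small for a set test. Members of the miRNA lists are precursor loci. Loci of the same miRNA, such as miR-1a-1 and miR-1a-2, therefore count as separate members although they share reads. Genomic positions (mm10) came from the GENCODE annotation of the same genome build. No position is given for precursors not found in it by name, nor for nuclear tRNA species, which have many loci.

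Alternatives were RLE scaling, clean-read totals in place of TMM, DESeq2 1.42.0, limma-voom, other filters on low counts, only the 2 groups compared, genome-matched reads only, a log2 fold change of at least 1, each class fitted alone, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were fits without the 3 libraries numbered 1, a term for these libraries, summing the loci of 1 miRNA, fitting each class alone without these libraries, thinning all libraries to the same number of clean reads, the mitochondrial tRNA parts as sets, and the tests of read ends. The fits were tested on simulated data of the observed spread (common biological coefficient of variation 0.468) in which 200 of 520 features had been changed: edgeR recovered 14.9% of features changed by 1 on the log2 scale, 76.1% of those changed by 2 and 100% of those changed by 3 in curcumin-treated against old mice, and called 0 features when nothing had been changed. Figures and share tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.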

Results

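Small RNAs of 15 to 45 nucleotides were sequenced from the atrial appendages of C57BL/6 mice. The libraries formed 3 groups of 3: young mice (5 months), old mice (18 months), and old mice that had taken 100 mg/kg of curcumin, a polyphenol of turmeric, each day between 12 and 18 months of age. PANDORA-seq first treats RNA with AlkB, which removes methyl groups that block reverse transcription, and with a kinase that repairs RNA ends for ligation, so that modified tRNA fragments enter the library. The title of the series is about tRNA-derived small RNA (tsRNA), curcumin and susceptibility to atrial fibrillation in the ageing atrium. Clean reads numbered 19707803, 15653512 and 12899427 in young replicates 1 to 3, 16123927, 17347658 and 16733364 in the old replicates, and 17509092, 17281690 and 14278019 in the curcumin replicates. The genome matched 73.7%, 67.0% and 65.0% of these reads in young mice, 72.2%, 65.5% and 66.0% in old mice, and 72.7%, 67.8% and 68.3% in curcumin-treated mice.

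Fragments of rRNA were the largest class, with 40.1% ± 6.14 of clean reads in young, 40.2% ± 4.15 in old and 37.7% ± 3.94 in curcumin-treated mice (SD, n = 3 here and for every group below). tsRNAs followed with 23.7% ± 5.88, 23.1% ± 6.08 and 26.2% ± 6.78, of which mitochondrial tRNAs made up 7.81% ± 1.97, 7.03% ± 0.338 and 7.95% ± 1.07 of clean reads. miRNAs took 2.63% ± 1.78, 2.30% ± 1.05 and 3.65% ± 0.519. The most abundant tsRNA was the other part of nuclear tRNA-Gly-GCC, at 146450, 152795 and 150240 CPM in the 3 groups, and among mitochondrial fragments it was the 5′ end of tRNA-Ser-GCT (mt-Ts2, chromosome M 11613 to 11671, plus strand), at 21114, 17503 and 25274 CPM. Further abundant tsRNAs were the other parts of tRNA-Gly-CCC and mitochondrial His-GTG, Glu-TTC and Val-TAC, the CCA ends of mitochondrial Val-TAC and Leu-TAG, and the 5′ ends of mitochondrial Ser-TGA and nuclear tRNA-Gly-GCC. Among miRNAs, miR-126a of endothelial cells stood at 6830, 7200 and 9024 CPM, and the muscle miRNA miR-1a-2 at 5165, 4669 and 7587 CPM. The other locus of this muscle miRNA, miR-1a-1, had the same mean over the 9 libraries, 5807 CPM, beside 7685 for miR-126a. Reads that matched both loci were divided between them, so the value of 1 locus understates miR-1a.

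**Figure D1:**
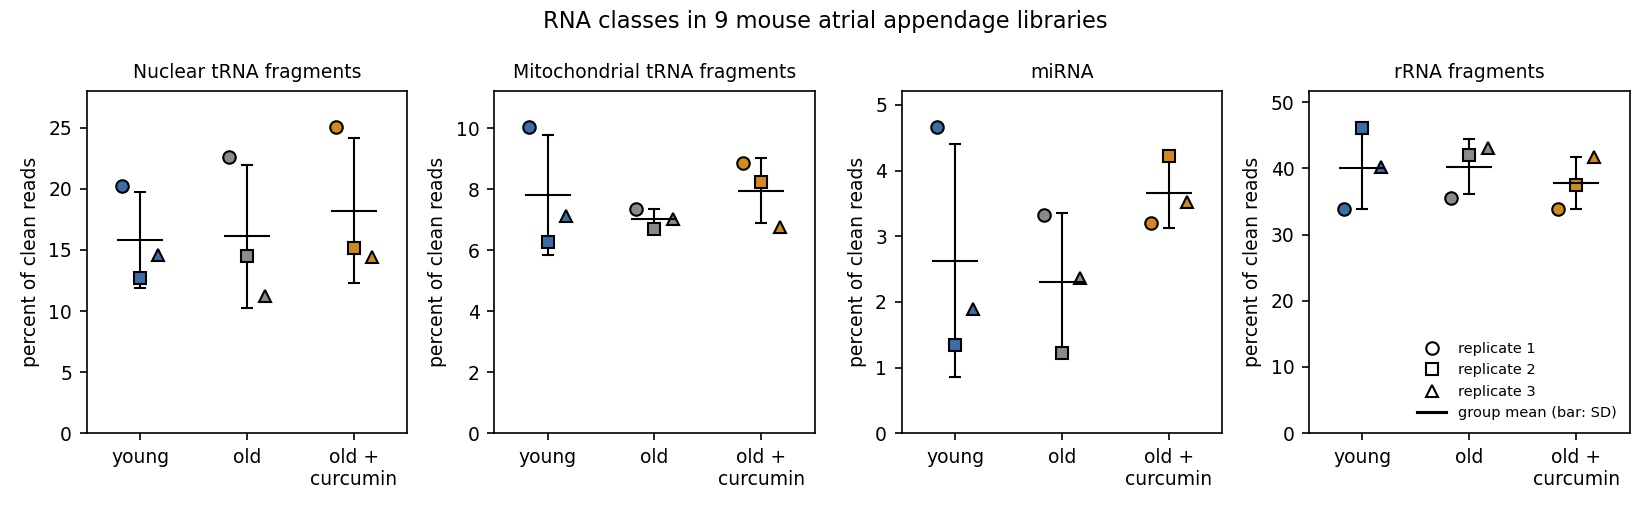
Percent of clean reads in nuclear tRNA fragments, mitochondrial tRNA fragments, miRNAs and rRNA fragments, for each of the 9 libraries by group, with group mean and SD as line and bar. The libraries numbered 1 had the highest share of nuclear tRNA fragments and the lowest share of rRNA fragments in every group.

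The 3 libraries numbered 1 stood apart from the other 6 in every group, as the plot of principal components shows, and this concerned the ends of tRNAs above all. Set against numbers 2 and 3 within groups, 120 of 520 features differed (edgeR, adjusted p under 0.05), 56 higher and 64 lower in the libraries numbered 1. Of 49 nuclear tRNA CCA ends 40 were lower, and of 22 mitochondrial 3′ ends without CCA 17 were higher. Of 209 miRNAs, 18 were higher and 3 lower. This contrast was chosen after the data were seen. Every comparison below holds 1 such library in each group.

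**Figure D2:**
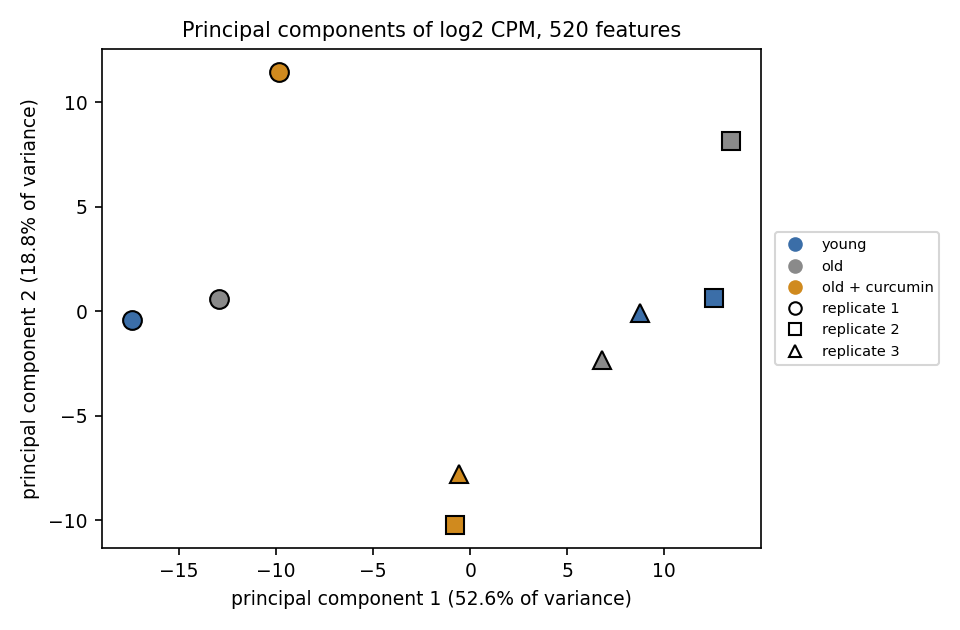
The first 2 principal components of log2 CPM over 520 features (52.6% and 18.8% of the variance), with colour for the group and symbol for the replicate number of the 9 libraries. The 3 libraries numbered 1 lie at the low end of component 1, apart from the other 6.

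The comparison of old with young mice asks which small RNAs differ with age. The miRNAs of the imprinted Dlk1-Dio3 region on chromosome 12, which are expressed from the maternal allele, fell as a set: 10 of 11 had lower fitted values in old mice, with a median log2 change of −0.60 (camera, adjusted p = 0.00642; adjusted p = 0.997 with an estimated correlation). Of all 209 miRNAs, 140 had lower fitted values in old mice, with a median of −0.15. miR-541 (chromosome 12, 109742409 to 109742498, in an intron of Mirg) stood at 9.11 ± 2.47 CPM in young and 4.64 ± 0.536 in old mice, miR-127 at 12.7 and 8.55, and miR-379 at 8.51 and 5.63. The red blood cell miRNAs fell as a set, with 4 of 4 lower and a median of −1.76 (adjusted p = 0.0112; adjusted p = 0.997 with an estimated correlation). The nuclear tRNA 5′ ends rose as a set, with 28 of 48 higher and a median of only 0.08 (adjusted p = 0.0336; adjusted p = 0.997 with an estimated correlation). With the replicate number as a block camera made the same 3 calls at the preset correlation, at adjusted p of 0.000309, 0.0247 and 0.0247. With an estimated correlation the block gave an adjusted p of 0.998 for each.

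No single feature passed: edgeR called 0 of 520 (0 tsRNAs, 0 miRNAs), with 5 at an unadjusted p under 0.05 where 26 would be expected by chance. DESeq2 called 0 (5 unadjusted) and limma-voom 0 (2 unadjusted), and edgeR with a replicate block 0. The smallest adjusted p was 0.999, so the features named next are given as values. The 5′ end of mitochondrial tRNA-Glu-TTC (mt-Te, chromosome M 14071 to 14139, minus strand) stood at 760 ± 186 CPM in young and 400 ± 141 in old mice, a log2 change of −0.93 (SE 0.32). The CCA end of mitochondrial tRNA-Asp-GTC (mt-Td, chromosome M 6942 to 7011, plus strand) stood at 231 ± 77.8 and 150 ± 25.5 CPM, and Y3 RNA, a small RNA bound by the Ro protein, at 658 ± 113 and 481 ± 69.7. The 3′ end of mitochondrial tRNA-Ser-TGA stood at 21.4 ± 20.0 and 55.5 ± 38.6 CPM. miR-181b-2 stood at 4.38 and 2.59 CPM, and miR-1981 and miR-700 lay below 1 CPM in both groups. The groups did not overlap for 24 features (4.62%), where chance gives 10% for libraries with no structure. The libraries numbered 1 stood apart in every group, so that percentage need not hold in these comparisons.

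The values of miR-144 and miR-451a, but not of all erythroid miRNAs, rested on 1 library. miR-144 and miR-451a, neighbours on chromosome 11 (78073005 to 78073070 and 78073170 to 78073241, plus strand) that are abundant in red blood cells, stood at 76.7 and 167 CPM in young replicate 1, against at most 8.02 and 16.5 CPM in any other library. Their log2 changes in old against young mice were −3.10 (SE 1.02) and −3.05 (SE 1.14), and without young replicate 1 they were −0.67 and −0.50. The other 2 members, miR-486a and miR-486b, were not highest in that library, with log2 changes of −0.47 (SE 0.42) and −0.46 (SE 0.42). Only miR-144 and miR-451a passed when adjusted over the list alone (2 of 4 members, 0 over all 520 features). Young replicate 1 also had the highest level among the 9 libraries for 9 of the 11 Dlk1-Dio3 miRNAs and 9 of the 10 miRNAs of the miR-17-92 group, against 79 of all 209 miRNAs and 0 of 6 in both the miR-30 and the inflammation list. The Dlk1-Dio3 call was lost without young replicate 1 (adjusted p = 0.727), old replicate 2 (0.252) or old replicate 3 (0.310). The erythroid call was lost without young replicate 1 (0.191), young replicate 3 (0.0714), old replicate 1 (0.0695) or old replicate 3 (0.0830), and without the 3 libraries numbered 1 (0.0821). The call of nuclear 5′ ends was lost without young replicate 1 (0.205), old replicate 2 (0.259), old replicate 3 (0.123) or curcumin replicate 1 (0.0621), and without the libraries numbered 1 (0.899). It was also lost when the loci of 1 miRNA were summed (0.0639).

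The other 39 lists did not pass in old against young mice (adjusted p from 0.0895 to 0.995). Of all 209 miRNAs, 140 had negative fitted values, with a median of −0.15, so negative values in the miRNA lists are not particular to them. Of the cardiac lists, 7 of 7 muscle miRNAs had negative fitted values (median −0.15, adjusted p = 0.158) and 9 of 11 fibrosis-linked miRNAs (median −0.01, adjusted p = 0.805). The let-7 family (11 of 12 negative), leukocyte miRNAs (7 of 9), miR-17-92 group (9 of 10), neuronal miRNAs (6 of 7), miR-30 family (4 of 6), senescence-linked (8 of 9) and atrial fibrillation-linked miRNAs (12 of 17) had adjusted p of 0.0895, 0.0895, 0.186, 0.186, 0.629, 0.876 and 0.719. Inflammation-linked miRNAs (4 of 6 positive) had an adjusted p of 0.249, and the endothelial list (4 of 7 positive) of 0.965. Mitochondrial tRNA fragments (50 of 88 negative), precursor tRNAs, cytoplasmic rRNA, nuclear CCA ends, 3′ ends and other parts had adjusted p of 0.186, 0.713, 0.187, 0.965, 0.629 and 0.172, and the 22 amino-acid lists of 0.0895 to 0.995. The share of tsRNA in clean reads was lower by 0.504 percentage points in old than in young mice (printed as −0.504, exact permutation p = 0.7), a difference far below the spread between libraries. It was −0.280, 2.19 and −3.42 within numbers 1, 2 and 3, and turned to 2.80, 0.486 and 1.92 without young replicate 1, old replicate 2 and old replicate 3. The share of Y RNA was 0.144% ± 0.00813 in young and 0.121% ± 0.00544 in old mice (exact permutation p = 0.1, the smallest possible; adjusted p = 1 over 20 shares), with differences of −0.0252, −0.0180 and −0.0279 within the numbers (exact sign-flip p = 0.25). In simulated data edgeR recovered 14.9%, 80.6% and 95.5% of features changed by 1, 2 and 3 on the log2 scale in this comparison, so that changes of about 2-fold were mostly not detectable.

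The comparison of curcumin-treated with old mice asks what the treatment changed at the same age. Senescence-linked miRNAs rose as a set: 9 of 9 were higher with curcumin, with a median log2 change of 0.62 (camera, adjusted p = 0.00749; adjusted p = 0.918 with an estimated correlation). They hold miR-29a, which targets collagen transcripts (378 ± 225 CPM in old and 597 ± 60.1 in curcumin-treated mice), and miR-146a, which targets inflammatory signalling (69.4 ± 26.3 and 130 ± 30.0 CPM). The test compared this list with all other features, of which 277 were tsRNAs. All 209 miRNAs had a median of 0.25, with 161 positive. The call therefore does not separate the list from miRNAs as a class. Nuclear tRNA-Glu fragments fell as a set, with 7 of 8 lower and a median of −0.47 (adjusted p = 0.0347; adjusted p = 0.918 with an estimated correlation). The most abundant of them, the other part of tRNA-Glu-CTC, stood at 3084 ± 1387 and 1992 ± 463 CPM. Mitochondrial tRNA fragments fell as a set under TMM scaling, with 48 of 88 lower and a median of −0.02 (adjusted p = 0.0404; adjusted p = 0.918 with an estimated correlation), while with clean-read totals 28 of 88 were lower and the call was lost (adjusted p = 0.0534). That scaling moved the median of all 520 features by 0.23 on the log2 scale.

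The features with the smallest p were mostly parts of mitochondrial tRNAs, and none passed: edgeR called 0 of 520 (0 tsRNAs, 0 miRNAs), with 21 at an unadjusted p under 0.05 where 26 would be expected by chance, DESeq2 called 0 (29 unadjusted) and limma-voom 0 (21 unadjusted). With the replicate number as a block edgeR called 0 as well. For mitochondrial tRNA-Glu-TTC the 5′ end stood at 400 ± 141 CPM in old and 989 ± 194 in curcumin-treated mice, a log2 change of 1.31 (SE 0.33, adjusted p = 0.525), and the CCA end at 3030 ± 720 and 1556 ± 69.3, a log2 change of −0.96 (SE 0.25, adjusted p = 0.525). CCA ends of Leu-TAG (mt-Tl2, chromosome M 11671 to 11741, plus strand; 4828 ± 1214 and 2318 ± 347 CPM), Thr-TGT (mt-Tt, 15289 to 15355, plus strand; 482 ± 87.7 and 273 ± 18.3) and His-GTG (mt-Th, 11546 to 11612, plus strand; 264 ± 58.8 and 148 ± 18.9) had log2 changes of −1.06, −0.82 and −0.83. The other part of Asn-GTT (mt-Tn, 5089 to 5159, minus strand) stood at 738 ± 217 and 322 ± 68.3 CPM and the 5′ end of Tyr-GTA (mt-Ty, 5260 to 5326, minus strand) at 96.0 ± 3.26 and 201 ± 88.0. Of nuclear tRNAs, the 5′ end of His-GTG stood at 243 ± 22.3 and 128 ± 22.6 CPM (log2 change −0.92, SE 0.27, adjusted p = 0.547), the only member of its list to pass when adjusted over the list alone (1 of 4, against 0 over all features), and the CCA end of Asp-GTC at 92.1 ± 39.4 and 43.1 ± 6.29. The Ensembl lincRNA class stood at 4136 ± 437 and 2785 ± 263 CPM. The groups did not overlap for 67 features (12.9%), where chance gives 10% for libraries with no structure.

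Higher fitted values with curcumin were common among miRNAs without passing the test. Of 209 miRNAs 161 had a positive log2 change (median 0.25), and the miRNA share of clean reads was 1.35 percentage points higher (exact permutation p = 0.2), being lower only within the pair numbered 1. Muscle miRNAs (7 of 7 positive, median 0.43), the miR-30 family (6 of 6, 0.42), fibrosis-linked (9 of 11, 0.42), atrial fibrillation-linked (16 of 17, 0.41), inflammation-linked (6 of 6, 0.41) and endothelial miRNAs (7 of 7, 0.32) had adjusted p of 0.0886, 0.0886, 0.0594, 0.0544, 0.142 and 0.157. miR-21a, a miRNA of fibroblasts and injury, stood at 58.8 ± 48.3 and 128 ± 30.9 CPM, and the smooth muscle miRNA miR-143 at 314 ± 161 and 578 ± 61.0. Red blood cell miRNAs (2 of 4 positive) had an adjusted p of 0.588, leukocyte miRNAs (9 of 9 positive) of 0.280, and the neuronal (6 of 7), miR-17-92 (9 of 10), let-7 (9 of 12) and Dlk1-Dio3 lists (7 of 11) of 0.142, 0.157, 0.490 and 0.658. Nuclear tRNA 5′ ends, 3′ ends, CCA ends (40 of 49 negative) and other parts, precursor tRNAs and cytoplasmic rRNA had adjusted p of 0.363, 0.945, 0.142, 0.795, 0.347 and 0.280, and the other amino-acid lists of 0.0594 to 0.970. The tsRNA share was 3.03 percentage points higher with curcumin (exact permutation p = 0.5), less than the spread between libraries; within numbers 1, 2 and 3 it was higher by 3.93, 2.26 and 2.91 (exact sign-flip p = 0.25, the smallest possible). Without curcumin replicate 1 the difference turned to −0.831, and over single left-out libraries it reached 6.45.

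Each of the 3 list calls hung on single libraries. The senescence call was lost without old replicate 2 (adjusted p = 0.157) or curcumin replicate 3 (0.0670), and the tRNA-Glu call without old replicate 2 (0.127), curcumin replicate 2 (0.107) or curcumin replicate 3 (0.0820). The mitochondrial call was lost without old replicate 3 (0.0937), curcumin replicate 2 (0.107) or curcumin replicate 3 (0.341), with a replicate block (0.0716), with a term for the libraries numbered 1 (0.0697) and with miRNA loci summed (0.0928).

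Without the 3 libraries numbered 1, a fit of 2 libraries per group chosen after the data were seen, 73 of 519 features changed between curcumin-treated and old mice (edgeR; 174 unadjusted), 34 up and 39 down. Of 210 miRNAs 30 rose and 1 fell, and of 275 tsRNAs 4 rose and 36 fell, among them 8 of 22 mitochondrial and 8 of 49 nuclear CCA ends. These directions hung on the scaling: with each class scaled and fitted alone, 13 miRNAs rose and 9 fell, and 24 tsRNAs rose and 17 fell, with 4 mitochondrial CCA ends down and 2 up and 4 nuclear CCA ends down and 1 up. In both fits 13 miRNAs rose, and 4 tsRNAs rose and 17 fell. The following were picked after their values were seen. miR-148a rose by 2.03 (SE 0.33) on the log2 scale and by 1.53 with miRNAs alone, the smooth muscle miRNA miR-143 by 1.43 (SE 0.28) and 0.88, miR-146a by 1.40 (SE 0.31) and 0.82, and miR-1a-2 by 1.21 (SE 0.27) and 0.68. miR-21a rose by 1.74 (SE 0.43) in the common fit and did not pass with miRNAs alone (1.27, adjusted p = 0.175). The mitochondrial CCA ends of Pro-TGG and Glu-TTC changed by −2.06 (SE 0.30) and −1.14 (SE 0.23), and by −1.61 and −0.74 with tsRNAs alone. In the pair of libraries numbered 1, which this fit had not used, 24 of the 73 features had the same sign (32.9%; 14 of 40 tsRNAs and 10 of 31 miRNAs), beside 36.6% of all 519 features tested. Old against young mice gave 0 features in the same fit (17 unadjusted).

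**Figure D3:**
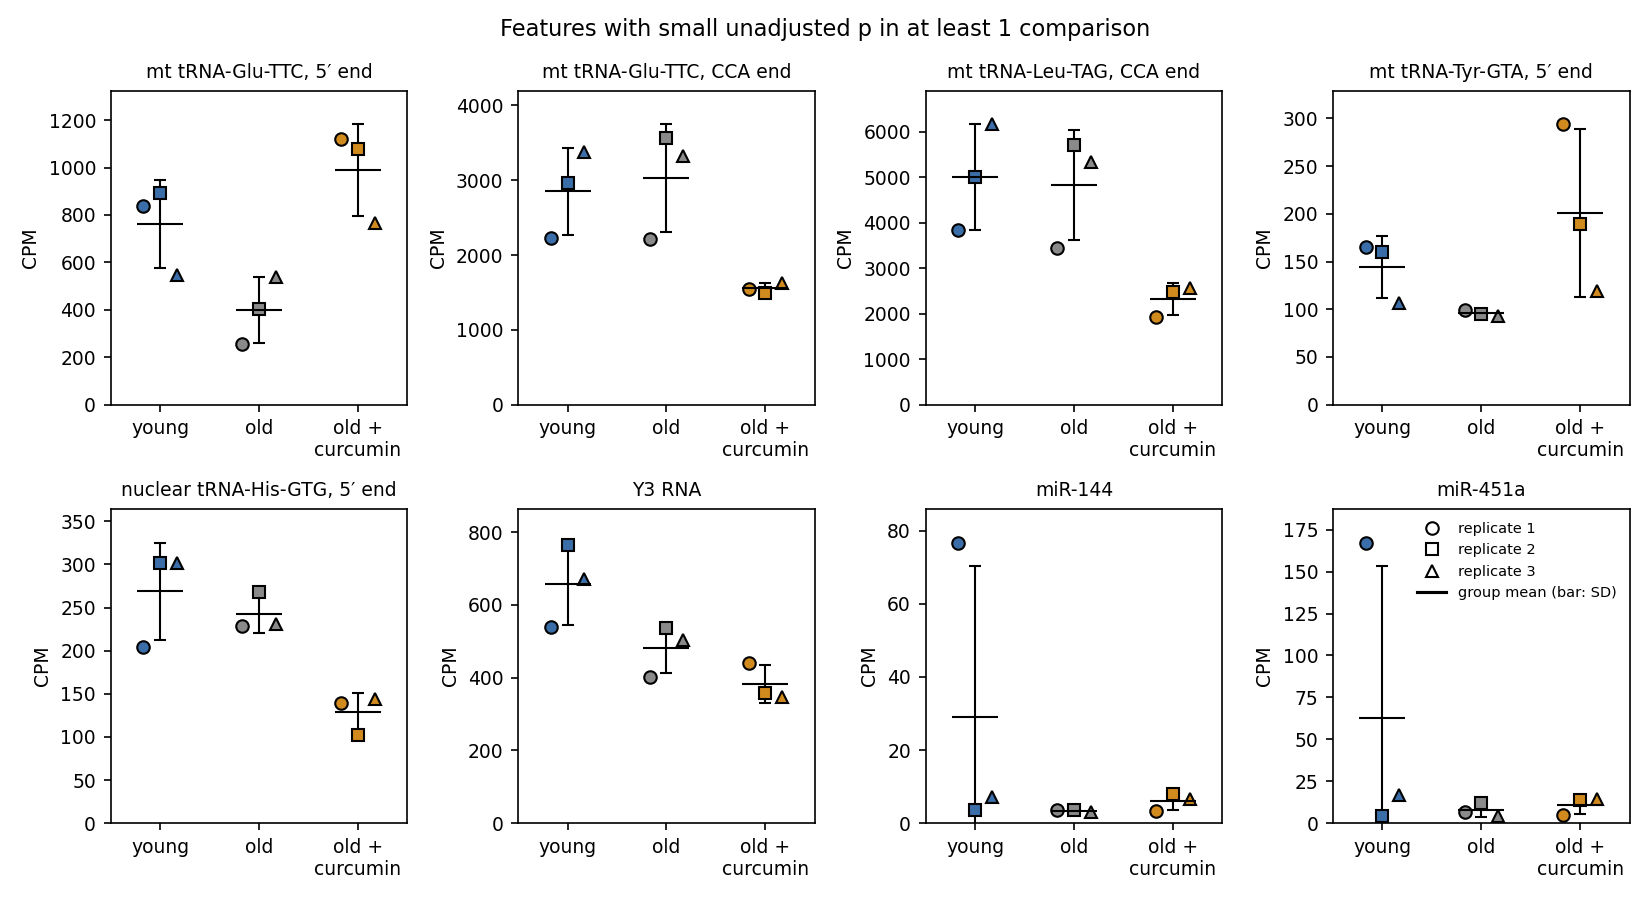
CPM of 8 features with a small unadjusted p in at least 1 comparison, in each of the 9 libraries by group, with group mean and SD as line and bar and symbols for the replicate number. The CCA ends of mitochondrial tRNA-Glu-TTC and Leu-TAG were lowest in the 3 curcumin libraries, and miR-144 and miR-451a were high in young replicate 1 alone.

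The comparison of curcumin-treated old mice with young mice asks how far the treated animals lay from the young state. Fragments of mitochondrial tRNAs fell as a set: 52 of 88 were lower, with a median log2 change of −0.11 (camera, adjusted p = 0.000174; adjusted p = 0.933 with an estimated correlation), while with clean-read totals, which moved the median of all features by 0.19, 41 of 88 were lower. Senescence-linked (9 of 9 higher, median 0.42, adjusted p = 0.00429), inflammation-linked (6 of 6, 0.78, adjusted p = 0.00704) and fibrosis-linked miRNAs (11 of 11, 0.38, adjusted p = 0.00900) rose as sets, with adjusted p = 0.933 with an estimated correlation for each. These lists share members: miR-146a stands in the first 2, the miR-29 family in senescence and fibrosis, and miR-21a in inflammation and fibrosis. Nuclear tRNA 5′ ends rose as a set (28 of 48 higher, median 0.26, adjusted p = 0.00514) and red blood cell miRNAs fell (4 of 4 lower, median −1.58, adjusted p = 0.00704), each with adjusted p = 0.933 with an estimated correlation. With the replicate number as a block camera made the same 6 calls at the preset correlation, at adjusted p between 0.00133 and 0.00868. With an estimated correlation the block gave an adjusted p of 0.941 for each.

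No feature passed in edgeR (0 of 520, 0 tsRNAs and 0 miRNAs, 19 at an unadjusted p under 0.05 where 26 would be expected by chance), in limma-voom (0, 16 unadjusted) or in edgeR with a replicate block (0). DESeq2 called 1 feature (30 unadjusted), the 5′ end of nuclear tRNA-His-GTG, which stood at 269 ± 56.2 CPM in young and 128 ± 22.6 in curcumin-treated mice (DESeq2 log2 change −1.08, adjusted p = 0.0327; edgeR −1.07, adjusted p = 0.669). It was also the 1 of 4 members of its list to pass when adjusted over the list alone (0 over all features). The CCA end of mitochondrial tRNA-Leu-TAG stood at 4998 ± 1165 and 2318 ± 347 CPM (log2 change −1.11, SE 0.27, adjusted p = 0.669). It passed in the fit with a term for the libraries numbered 1 (−1.10, adjusted p = 0.0486), which was added after the data were seen. The CCA ends of mitochondrial Glu-TTC (2852 ± 584 and 1556 ± 69.3 CPM), Thr-TGT (420 ± 7.37 and 273 ± 18.3) and Asp-GTC (231 ± 77.8 and 135 ± 21.9) and the other part of Asn-GTT (601 ± 188 and 322 ± 68.3) had values in the same direction, as had Y3 RNA (658 ± 113 and 382 ± 51.9) and miR-541 (9.11 ± 2.47 and 3.25 ± 1.26). The other part of tRNA-Lys-TTT stood at 145 ± 9.23 and 238 ± 57.1 CPM, and the 5′ end of tRNA-Arg-CCT at 0.257 and 1.23. The groups did not overlap for 54 features (10.4%), where chance gives 10% for libraries with no structure.

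The 36 other lists did not pass (adjusted p from 0.0548 to 0.900). They include atrial fibrillation-linked (12 of 17 positive, adjusted p = 0.0915), endothelial (6 of 7, 0.119), miR-30 (6 of 6, 0.161), muscle (5 of 7, 0.481), leukocyte (2 of 9, 0.800), neuronal (5 of 7, 0.506), let-7 (5 of 12, 0.576) and Dlk1-Dio3 miRNAs (1 of 11, 0.161) and nuclear tRNA-His fragments (0 of 4, 0.0548). Nuclear tRNA 3′ ends (34 of 38), CCA ends (9 of 49) and other parts (28 of 50), precursor tRNAs (0 of 4) and cytoplasmic rRNA (2 of 5) had adjusted p of 0.647, 0.145, 0.506, 0.149 and 0.848, and the 22 amino-acid lists of 0.0548 to 0.900. For the miR-17-92 group the test gave a direction opposite to the median of −0.31 (2 of 10 positive, adjusted p = 0.674). Without young replicate 1 the calls of mitochondrial tRNAs (adjusted p = 0.126), nuclear 5′ ends (0.791) and red blood cell miRNAs (0.338) were lost, and miR-144 and miR-451a changed sign from −2.28 and −2.53 to 0.15 and 0.04. The mitochondrial call was also lost without curcumin replicate 3 (0.0618), as was the inflammation call (0.0756), and the erythroid call without curcumin replicate 1 (0.135). The senescence call was lost without young replicate 2 (0.110), and the fibrosis call without young replicate 2 (0.321), without young replicate 3 (0.0913) or with clean-read totals (0.0528). Without the 3 libraries numbered 1 the calls of nuclear 5′ ends (0.848) and red blood cell miRNAs (0.851) were lost, and 67 of 519 features changed (162 unadjusted), 37 up and 30 down. They were 28 tsRNAs (4 up, 24 down), 35 miRNAs (33 up, 2 down) and 4 others, and 15 of the 67 had the same sign in the pair numbered 1, beside 35.1% of all 519 features tested. With each class scaled and fitted alone, 16 tsRNAs rose and 12 fell, and 18 miRNAs rose and 10 fell, among the latter miR-486a (−1.33, adjusted p = 0.00120) and miR-486b (−1.27, adjusted p = 0.00169).

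Whether curcumin moved age-related features back was asked of the 2 sets of log2 changes. The share planned for this, among features changed with age, had no value because 0 features passed. Over all 520 features, 61.3% had opposite signs in old against young and curcumin against old mice (58.5% of tsRNAs, 66.0% of miRNAs). Both comparisons use the same old libraries, which alone gave 66.3% (SD 2.17) in 100 simulations without any change and with libraries drawn independently. Simulations added after the result was seen, with effects of the replicate number shared by the groups, gave 66.9% (SD 1.86). The measured share lay below the central 95% of both (62.3% to 70.5% and 63.5% to 70.3%), and so was not above what shared libraries give. The added simulations drew each feature independently, whereas single left-out libraries moved the measured share between 38.9% and 76.6%. These ranges are therefore too narrow to show that the measured share was lower than unchanged groups give. Across features, which are not independent replicates, Pearson's r was −0.38 and Spearman's rho −0.38, against simulated means of −0.49 and −0.46 (−0.50 and −0.48 with effects of the number), and the covariance was −0.0850 against −0.176 (−0.121). Without young replicate 1 the share was 38.9% and r was 0.06. The 5′ end of mitochondrial tRNA-Glu-TTC was the feature named in both comparisons by its p, at 760, 400 and 989 CPM in young, old and curcumin-treated mice. It passed in neither comparison. Low values in the shared old libraries alone would give both changes, so its values are no evidence of a reversal.

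**Figure D4:**
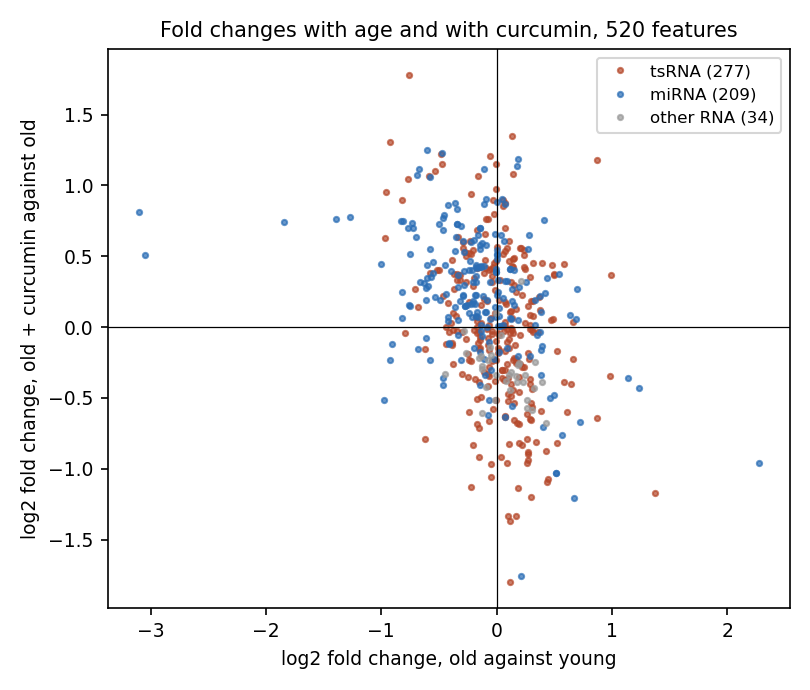
Log2 fold change of old against young mice (x axis) and of curcumin-treated against old mice (y axis) for 277 tsRNAs, 209 miRNAs and 34 other features, 1 point per feature. Opposite signs were found for 61.3% of features, against 66.3% in simulations where nothing had changed.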

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

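Leaving out any 1 of the 9 libraries left 0 features in each comparison, but all 12 list calls were ended by leaving out some 1 library, 6 of them by young replicate 1. With an estimated correlation 0 lists were called in each comparison, and with fry 0. Over single left-out libraries the lists called ranged from 2 to 12 in old against young mice, from 0 to 14 in curcumin-treated against old mice and from 5 to 11 in curcumin-treated against young mice. Without the 3 libraries numbered 1 (chosen after the data were seen) 73 and 67 features were called in curcumin-treated against old and against young mice, among them 40 and 28 tsRNAs and 31 and 35 miRNAs, and 21 and 19 lists. DESeq2 called 1 feature in curcumin-treated against young mice, a tsRNA, and the term for the libraries numbered 1 called 1, a tsRNA. A sign change of a value that did not pass was counted only where the value with all libraries exceeded 1 SE or the new value passed, a rule chosen for these tests.

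With the replicate block 0 features were called in each comparison (5, 41 and 40 unadjusted), and the call of mitochondrial tRNA in curcumin-treated against old mice was lost, with no other call changed. Old and young libraries of the same number deviated together, with all correlations above a limit of 0.1 (0.81, 0.62 and 0.27). So did curcumin and young libraries (0.33, 0.19 and 0.28). Curcumin and old libraries fell below the limit, but only in number 2 (0.27, −0.07 and 0.37). Numbers 2 and 3 also correlated across numbers, at 0.54 for young 3 with old 2 and 0.38 for young 2 with old 3. Young 2 with curcumin 3 and young 3 with curcumin 2 gave 0.22 each. Old 3 with curcumin 2 gave 0.49, and old 2 with curcumin 3 gave 0.05. Pairing by number was therefore not shown for numbers 2 and 3. The best match of 6 of the 9 libraries carried its own number, a hint from the data and not from the design.

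The share of features with opposite signs was 69.2% with clean-read totals, 64.2% with the replicate block, 58.5% for tsRNAs and 66.0% for miRNAs, and 38.9% to 76.6% over single left-out libraries. The correlation was −0.43 with clean-read totals, −0.45 with the replicate block, and −0.74 to 0.0582 over left-out libraries. The tsRNA share of old against young mice was 0.277 points without mitochondrial tRNA and −3.92 to 2.80 over left-out libraries (2.80, 0.486 and 1.92 without young replicate 1, old replicate 2 and old replicate 3). The share of curcumin-treated against old mice ranged from −0.831 (without curcumin replicate 1) to 6.45.

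With genome-matched reads only, the CCA ends of mitochondrial Thr-TGT and His-GTG changed sign to 0.0832 and 0.22 in curcumin-treated against old mice. This setting removes most of these reads, since CCA is not in the genome. Of mitochondrial CCA-end reads, 10.8%, 7.91% and 9.01% matched in old replicates 1 to 3, and 12.3%, 19.2% and 15.0% in curcumin replicates. The other part of mitochondrial Val-TAC changed to −0.16 against young mice in this setting. The cause of these sign changes was not tested. In curcumin-treated against young mice miR-451a and miR-144 were 0.42 and 0.48 without the libraries numbered 1. Their ranges over left-out libraries were −2.996 to 0.0358 and −2.72 to 0.15, the upper ends without young replicate 1. Reversals of lists are given by the direction of the set test, which compares a list with all other features and need not follow the sign of its mean. Mean log2 changes where it turned in old against young mice were −0.0103 (without the libraries numbered 1) and −0.12 (without young replicate 1) for nuclear 5′ ends, −0.38 (without young replicate 1) and −0.32 (without old replicate 2) for CCA ends, −0.22 (without old replicate 2) for other parts, and −0.36, −0.41 and −0.36 (without young replicate 1) for tRNA-Ala, tRNA-Pro and tRNA-Ser (for tRNA-Ser the mean with all libraries was already −0.0379). Over left-out libraries these lists ranged from −0.12 to 0.27, −0.38 to 0.41, −0.22 to 0.24, −0.37 to 0.0800, −0.52 to 0.43 and −0.36 to 0.23. In curcumin-treated against old mice they were 0.82 (without curcumin replicate 2) for nuclear 3′ ends, whose mean was 0.49 with all libraries and turned to −0.82 without curcumin replicate 1, and 0.29 (without old replicate 2, lowest −0.16) for other parts. Against young mice they were −0.0216 (without the libraries numbered 1) and −0.00751 (without young replicate 1, highest 0.47) for 5′ ends, −0.59 (without the libraries numbered 1) and −0.79 (without curcumin replicate 1, highest 0.79) for 3′ ends, and −0.26 (without the libraries numbered 1) for other parts. The cause of these reversals was not tested. The share planned among features changed with age had no value in any setting.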

Other observations

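The tests of mitochondrial tRNA ends in this part were chosen after the results were seen. The CCA ends of mitochondrial tRNAs, which mark mature 3′ ends, were lower in 17 of 22 species in curcumin-treated than in old mice, with a median log2 change of −0.37 (camera, unadjusted p = 1.37e-08, unadjusted p = 0.0387 with an estimated correlation and 0.0255 by fry). Against young mice 20 of 22 were lower (unadjusted p = 1.37e-11, 0.0195 with an estimated correlation and 0.0107 by fry). As a share of clean reads, mitochondrial CCA ends differed by −0.282, 0.270 and −0.611 percentage points between curcumin-treated and old mice within numbers 1, 2 and 3 (exact permutation p = 0.4), and 5′ ends by 0.776, 2.00 and 0.752 (exact permutation p = 0.2). With the replicate block the unadjusted p of the CCA-end sets with an estimated correlation were 0.0773 and 0.0483. Without the libraries numbered 1, CCA ends were lower in 16 and 17 of 22 species. The unadjusted p were then 0.00384 and 0.00125 by camera, 0.333 and 0.289 with an estimated correlation, and 0.0645 and 0.0664 by fry. Mitochondrial 5′ ends were lower in 19 of 22 species in old than in young mice (unadjusted p = 8.77e-07, 0.0943 with an estimated correlation and 0.199 by fry). Without the libraries numbered 1, 13 of 22 were lower (camera, unadjusted p = 0.263, 0.507 with an estimated correlation and 0.489 by fry). Reads of mitochondrial 5′ ends per read of CCA ends numbered 2.44, 1.36 and 1.23 in young replicates 1 to 3, 1.94, 1.09 and 1.07 in old replicates, and 2.98, 1.95 and 2.04 in curcumin replicates. The log2 change from young to old mice was −0.33, −0.32 and −0.21 within numbers 1, 2 and 3 (exact permutation p = 0.5, exact sign-flip p = 0.25, the smallest possible). This ratio pools 22 species, of which 3 held 86.8% of the 5′ end reads. Over the 9 libraries Ser-GCT had 2905780 5′ end and 6313 CCA-end reads, and Val-TAC had 2232 and 929781. The pooled ratio thus largely sets 5′ ends of some tRNAs against CCA ends of others.

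All tests of the libraries numbered 1 were chosen after this pattern was seen, and only the reading of the thinned libraries was written before its result. They set apart 120 features, while the highest count of the 26 other choices of 1 library per group was 0, but these libraries had been picked for standing apart, so this cannot tell whether library batches that follow the replicate number are the cause. The libraries numbered 1 had 38.0% (young), −5.38% (old) and 10.96% (curcumin) more clean reads than the mean of the other 2, but the number of reads is not a likely cause, since 115 features were set apart with all 9 libraries thinned to the same number of clean reads, 112 of them among the 120. Trimming of the CCA from tRNA 3′ ends could not be the whole cause, since 47 of the features were neither 3′ ends nor CCA ends, and no biological explanation was tested.

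The tests of the features called in curcumin-treated against old mice without the libraries numbered 1 were also chosen after the result was seen. An effect of curcumin shared by the 3 replicate numbers might underlie them, but 24 of 73 had the same sign in the pair numbered 1, near the 36.6% of all features tested, and 1 library per group decides nothing. A shift of all miRNAs against all tRNA fragments that moves the common scaling could explain part of them: with each class scaled and fitted alone, 21 of 40 tsRNAs and 13 of 31 miRNAs were called in the same direction as before, the surplus of falling tsRNAs turned, and the size of that part stays open. Of the 3 splits of the 4 libraries into 2 and 2, only 1 (the real split) gave a count as large, and the others gave 0, which are too few splits to judge chance.

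The mitochondrial end ratio was higher in curcumin-treated than in old mice within each number, by 0.62, 0.84 and 0.93 on the log2 scale (exact permutation p = 0.1, the smallest possible), and of its tests only that on genome matching had its reading written before the result and left as it was. Handling or library steps that change the ends of all tRNAs alike could not be excluded. The nuclear ratio changed by −0.73, 0.24 and 0.25 (mean −0.0817, SD 0.56). The mitochondrial change exceeded it by 1.35, 0.60 and 0.68 within the numbers (mean 0.88, SD 0.41). But nuclear CCA ends had lower values with curcumin in 40 of 49 cases, with a median of −0.38 beside −0.37 for mitochondrial ones. A few species that take most reads could not be excluded either: without the 3 species with most 5′ end reads the mean was 0.58, from values of 1.70, −0.13 and 0.18 (SD 0.98), and for those 3 alone it was 0.41 (SD 0.38), by a reading tightened after the value was seen. The ratio was higher on average in 19 of 22 species (median 0.57), in 10 of them within all 3 numbers, but this rested on number 1, with 22, 11 and 15 species higher in numbers 1, 2 and 3. With genome-matched 5′ end reads alone the mean was 0.80, which met the reading written against reads that do not match the genome but decides nothing, because at least 99.99% of 5′ end reads match.

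Splits of the 6 libraries of a comparison into 3 and 3, of which there are 10, gave as many called features, tsRNAs and miRNAs as the real split in 10 of 10 cases in each comparison, since the real counts were 0. The highest counts of the other splits were 20 features, 4 tsRNAs and 15 miRNAs in old against young mice and 0 in the other 2 comparisons. Lists were called as often as in the real split (3, 3 and 6) in 9, 9 and 8 of the 10 splits, with up to 20, 23 and 26 lists in the other splits. Old and young libraries of the same number passed the limit of 0.1 used above, as did curcumin and young libraries. Numbers 2 and 3 of these groups passed it across numbers as well. The real split parts all 3 pairs of the same number, as 3 other splits do. Among those the highest counts were 0 features and 5 lists in old against young mice and 0 features and 26 lists in curcumin-treated against young mice. The 20 features came from 1 of the 4 splits that put both libraries numbered 1 in 1 group, while the other 3 gave 0. Counts of lists several times the real one point to a structure of the samples, whose source was not tested by the splits. The splits are too few for a share under 0.05.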
